A study of Rattus norvegicus with 12 samples.

How the data were processed

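The series held 12 RNA-seq libraries of rat tissue, 3 each from GelMA and MFN+GelMA implants at 2 and 4 weeks. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with Ribo-Zero, and libraries were made with the TruSeq stranded total RNA kit. Per the submitters' processing notes the tools were cutadapt 1.9.3, HISAT2 and Cuffdiff, with the rn6 rat genome. Versions of the aligner and of Cuffdiff, the annotation and the strand setting are not given in the sources used here.

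A single deposited table gave 22062 rows of genes with gene IDs, symbols, loci and values for each library. Per the file headers, 12 columns held FPKM, the unit that was tested. The other 12 deposited columns are headed Counts, and their values are a count-like signal, not whole numbers: between 99.35% and 99.51% of the positive values of a library lay within 0.05 of a multiple of 1 step (0.875 to 1.08 between libraries), and 204 positive values were under 0.5 of a step. A count model was therefore not used. Dividing each library's total by its step gave 11405123 to 14043168 fragments. The MFN+GelMA 2W libraries (11902316 to 12320534) lay below all 4W libraries (12433568 or more). All 24 value columns were mapped to samples by name. At this depth a gene near 1 FPKM rests on few fragments, so the values of such genes are the least precise.

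Rows sharing a symbol were summed (233 symbols on 498 rows), which gave 21797 genes, and 18 rows without a symbol kept their ID. Of the rows 2559 shared a locus with another row, where the division of reads between overlapping genes could not be checked. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested (12270 genes). Of 525 symbols in the gene lists 19 were not analysed here. Gene IDs, symbols and rn6 loci are those of the deposited table.

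The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, with 1 mean per group over all 12 libraries, an intensity trend in the empirical Bayes step (8 residual and 3.28 prior degrees of freedom) and no further scaling. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 contrasts were MFN+GelMA against GelMA at 2 weeks, at 4 weeks, averaged over both and as an interaction, and 4 against 2 weeks in each material. These choices, the 25 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold with a mean of at least 2 FPKM and a proper symbol, and up to 4 members per list with the smallest unadjusted p. A few genes that this rule selected are not reported here.

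The lists covered skeletal muscle fibre, white adipocyte, keratinocyte and hair follicle, macrophage, giant cell and osteoclast, neutrophil, T cell, B and plasma cell, mast cell, endothelial, smooth muscle and pericyte, Schwann cell and nerve, and red blood cell markers, and genes of collagen and matrix, myofibroblast and TGF-beta response, matrix degradation, pro-inflammatory cytokines, alternative macrophage activation, interferon response, MHC class II, cell cycle, muscle regeneration, oxidative phosphorylation, immediate early and heat shock response, and cartilage and bone. The 22 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Of the 132 tests of a list in a contrast 65 passed, 0 of them with an estimated correlation. With fry 28 of the 132 passed, some of them not called by camera. Fry called 0 lists at 2 weeks, 8 at 4 weeks, 6 in the average and 2 in the interaction. For time it called 3 in GelMA and 9 in MFN+GelMA. Fry tests whether the genes of a list move, on balance, one way and does not compare the list with other genes.

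The code was tested on simulated values for the 4-week comparison with 12061 genes in the fit. Of 100 genes changed by a log2 fold change of 1 it recovered 79, and of 100 changed by 2 it recovered 94, with median estimates of 1.01 and 1.97, and 10 of 11841 unchanged genes were called. For the 2-week comparison, simulated without change, 0 genes were called. A simulated list of 20 genes shifted by 0.5 had a camera p of 5.12e-19 and an unshifted list 0.403. The changed genes were drawn from those with a mean of at least 2 on the log2 scale, so recovery of lower genes was not measured. All genes were simulated independently, while the real lists had estimated correlations of 0.089 to 0.85. The simulation therefore cannot show how camera at its preset correlation behaves on the real lists.

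The alternatives were other filters and pseudocounts, 3 scalings of the FPKM, fits with only the libraries compared, without the trend, with robust variances, array weights or a block for the replicate number, a muscle covariate, other thresholds, rows kept apart, and each library left out in turn. After the data had been seen, fits that set listed zeros of Col1a1 and Col3a1 to missing, that used the Counts columns, that left out 2 or 3 libraries together and that used a fat covariate were added. The collagen list was also tested without these 2 genes. A permutation over genes that set the giant cell list against the macrophage list was replaced, after its result was known, by a comparison of list means per library, since the genes are not independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.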

Results

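RNA sequencing measured gene expression in rats at 2 and 4 weeks, written 2W and 4W in the labels, in tissue named there as subcutaneous tissue or muscle. The control implant was GelMA (gelatin methacryloyl, a hydrogel that is cured with light). The test implant was MFN+GelMA, where the labels do not spell out MFN and the title of the series names a microfiber beside GelMA. The 12 libraries formed 4 groups of 3, called GelMA 2W, MFN+GelMA 2W, GelMA 4W and MFN+GelMA 4W here. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

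The deposited count-like values summed to 11174499 to 13025655 per library. The smallest steps between values corresponded to about 11405123 to 14043168 fragments per library before scaling. Between 11323 and 11773 genes per library reached 1 FPKM, a measure of fragments per length of transcript and library size. The 10 most abundant genes took 13.6% to 22% of the count-like total, and mitochondrial genes took 17.8% (GelMA 2W replicate 3) to 32.7% (MFN+GelMA 4W replicate 1) of summed FPKM. A total of 12270 genes entered the tests. On the log2(FPKM + 1) scale, Pearson's r across genes, which are not independent replicates, was 0.941 to 0.98 within groups and 0.876 to 0.962 between groups. On the first principal component, which held 35.1% of the variance, the MFN+GelMA 4W libraries lay at 44 to 50.1 and the other 9 libraries at -44.2 to -0.53.

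A few libraries carried markers of other tissues, which bear on the gene groups below. Acta1, skeletal muscle actin, stood at 275 FPKM in MFN+GelMA 2W replicate 2 and below 1 FPKM in the other 11 libraries, and the skeletal muscle fibre list averaged 5.67 there on the log2 scale against 1.43 to 2.11 elsewhere. Adipoq, which encodes the fat hormone adiponectin, reached 2118 FPKM in GelMA 4W replicate 2, beside 17.97 in the lowest library of that group. It also separated the materials at each week. At 2 weeks it was 9.245 FPKM or more in GelMA and at most 6.311 FPKM in MFN+GelMA. At 4 weeks the highest MFN+GelMA library had 10.35 FPKM. GelMA 2W replicate 3 had the least endothelial signal of its week. The cadherin gene Cdh5 stood there at 27.35 FPKM against 90.48 or more in the other 2W libraries, and Kdr, a receptor for vascular endothelial growth factor, at 5.58 FPKM against 14.38 or more. Krt5, a keratin of the basal epidermis, was listed at 0 in every library. Col3a1 was listed at 0 in 3 GelMA libraries and Col1a1 in 1 of them, beside 6304 to 13992 and 3449 to 8848 FPKM in the others, so a listed 0 can be a failed estimate.

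**Figure D1:**
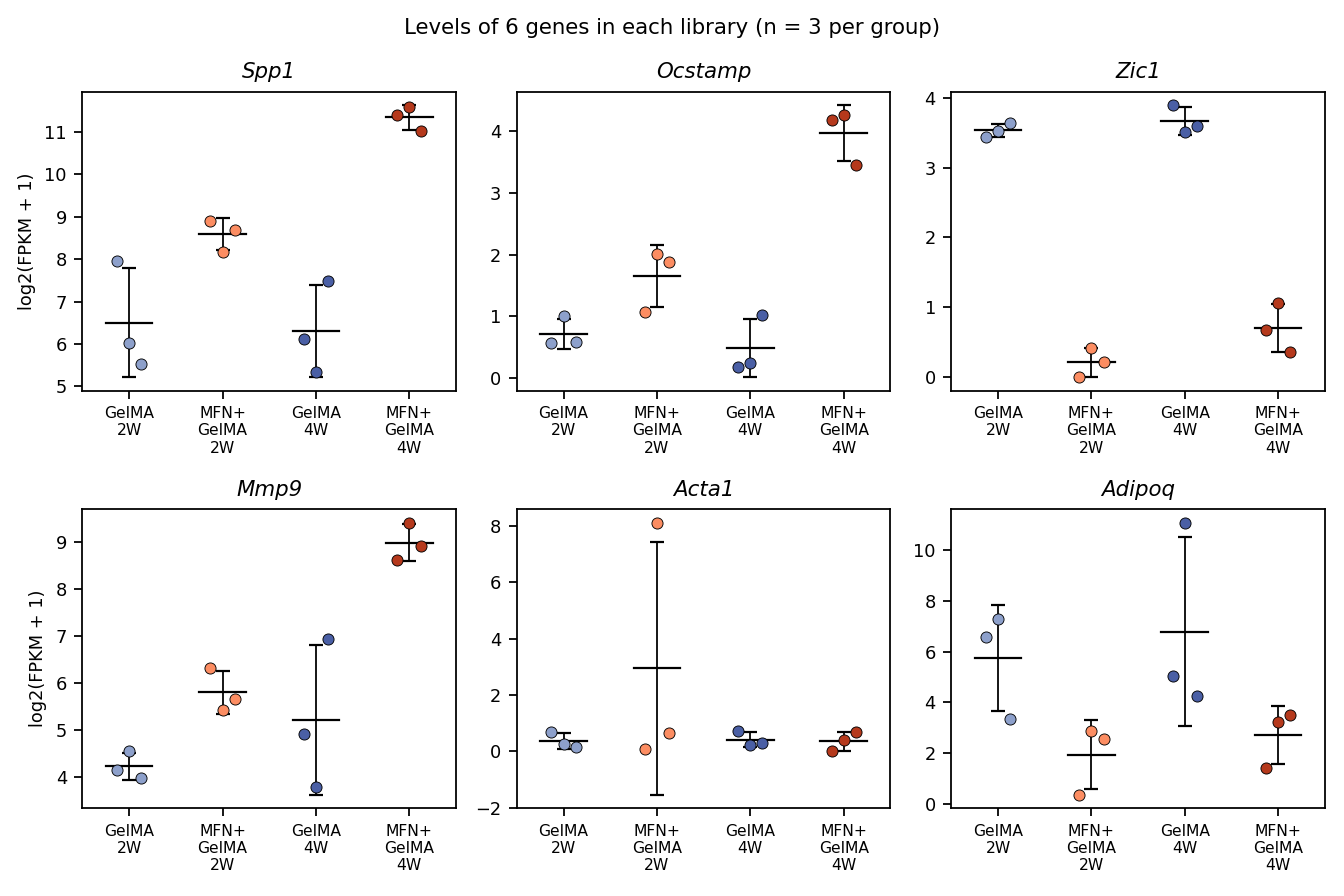
Levels of Spp1, Ocstamp, Zic1, Mmp9, Acta1 and Adipoq on the log2(FPKM + 1) scale (vertical axis) in each library of the 4 groups (horizontal axis); points are libraries, lines are group means and bars are SD (n = 3). Spp1, Ocstamp and Mmp9 stood highest in MFN+GelMA 4W, Zic1 was lower in both MFN+GelMA groups, and Acta1 and Adipoq were each far higher in 1 library. Adipoq was also lower in each MFN+GelMA library than in each GelMA library of the same week.

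The first comparison asked how adding MFN to the hydrogel changed the tissue at 2 weeks. The developmental transcription factor gene Zic1 fell in MFN+GelMA. It stood at 10.6 ± 0.791 FPKM (SD, n = 3) in GelMA 2W and 0.165 ± 0.167 FPKM (SD, n = 3) in MFN+GelMA 2W. The stress-induced mTOR inhibitor gene Ddit4 rose from 11.1 ± 2.65 to 42.1 ± 10.5 FPKM (SD, n = 3). Cxcl6, a chemokine gene that attracts neutrophils, rose from 0.265 ± 0.274 to 43.4 ± 33.2 FPKM (SD, n = 3). The elastin gene Eln fell from 218.8 ± 98.5 to 40.9 ± 7.77 FPKM (SD, n = 3).

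By limma, the log2 fold change of Zic1 (ENSRNOG00000014644; rn6 chromosome 8, 98734294 to 98738446) was -3.32 (SE 0.20, adjusted p = 1.35e-05). For Ddit4 limma gave 1.83 (SE 0.19, adjusted p = 0.00297). Cxcl6 changed by 4.54 (SE 0.70, adjusted p = 0.0166) and Eln by -2.29 (SE 0.36, adjusted p = 0.0182) in the same limma test. Tnnt2, a troponin of heart and embryonic muscle, rose by 1.85, and Meox1, a mesenchymal homeobox gene, by 1.77 on the log2 scale. The retinoic acid synthesis gene Aldh1a3 fell by 1.66, C1qtnf7 by 1.77, the peptidase inhibitor gene Pi16 by 1.73 and the adhesion gene Cadm1 by 1.62 on the log2 scale. Here and below, coordinates are the loci of the deposited table, which does not state whether starts count from 0 or 1, and fold changes on the log2(FPKM + 1) scale understate the change of low genes.

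Among the lists fixed in advance, the matrix degradation list was higher in MFN+GelMA at 2 weeks. Of its 23 tested genes 2 rose, Timp1, an inhibitor of matrix proteases, by 2.08 and the aggrecan-cleaving protease gene Adamts4 by 1.53 on the log2 scale (7 rose when adjusted over the list alone). Its camera adjusted p was 0.0021, and 0.74 with an estimated correlation. The Timp1 locus is shared with 3 other genes of the table. The interferon-stimulated list was lower, with a median log2 fold change of -0.72 over 24 genes and none past the test over all genes (2 fell when adjusted over the list alone), at a camera adjusted p of 1.04e-05 and an adjusted p of 0.74 with an estimated correlation. The neutrophil list (7 genes, median 1.26, adjusted p = 0.0128 by camera) and the MHC class II list (15 genes, median 0.29, adjusted p = 0.0234) were higher with no member past the test over all genes, while 3 and 4 members rose when adjusted over the list alone, and 1 of the MHC class II genes fell. Without GelMA 2W replicate 1 or MFN+GelMA 2W replicate 3, the camera adjusted p of the MHC class II list was 0.113 and 0.0755. With an estimated correlation the adjusted p of both was 0.74.

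Other lists lost their calls without single libraries. The skeletal muscle fibre list (11 genes, median 1.4, camera adjusted p = 0.0021) was higher with none past the test over all genes and 1 higher when adjusted over the list alone. Without MFN+GelMA 2W replicate 2 its adjusted p was 0.71 in the opposite direction. The endothelial list (18 genes, median 0.58, camera adjusted p = 0.00122) and the smooth muscle and pericyte list (16 genes, median 0.55, camera adjusted p = 0.0021) had adjusted p-values of 0.455 and 0.443 without GelMA 2W replicate 3. None of their genes passed over all genes, and 1 endothelial gene rose when adjusted over the list alone. The collagen and extracellular matrix list was higher (28 genes, 1 fell, median 0.28, camera adjusted p = 0.0306; 5 rose and 1 fell when adjusted over the list alone), as was mitochondrial oxidative phosphorylation (34 genes, none past the test, median 0.13, camera adjusted p = 0.0128). The white adipocyte list (19 genes, median -0.42, camera adjusted p = 0.0468) and the immediate early and heat shock list (22 genes, median -0.21, camera adjusted p = 0.0275; 2 fell when adjusted over the list alone) were lower. Each of these 4 lists lost its call without at least 1 library. The adjusted p-values rose up to 0.371 for collagen without GelMA 2W replicate 2, 0.101 for oxidative phosphorylation without MFN+GelMA 2W replicate 3, 0.329 for white adipocyte without GelMA 2W replicate 2 and 0.316 for immediate early without MFN+GelMA 2W replicate 2. Without Col1a1 and Col3a1, which carry the listed zeros, the collagen list had a camera adjusted p of 0.0342 at 2 weeks. For all 7 lists of this paragraph the adjusted p with an estimated correlation was 0.74. With fry 0 of the 22 tested lists passed at 2 weeks.

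In all, 61 of 12270 genes changed at 2 weeks by limma, 21 higher and 40 lower, and 1742 had an unadjusted p under 0.05. Of all tested genes 18.2% had groups that did not overlap, where chance would give 10%. The count of changed genes rested on single libraries. It was 22 without MFN+GelMA 2W replicate 1, 24 without GelMA 2W replicate 2, 29 without MFN+GelMA 2W replicate 3, 40 without MFN+GelMA 4W replicate 3, 93 without GelMA 4W replicate 2, 162 without MFN+GelMA 2W replicate 2, and 386 without the 3 libraries with muscle, fat or low endothelial signal. Of the 20 genes selected for naming 9 passed in each of the 12 fits that left out 1 library, among them Zic1, Ddit4, Tnnt2, Aldh1a3, C1qtnf7, Pi16 and Cadm1. With only the 6 libraries of 2 weeks in the fit 9 genes passed in all, and of these 7 genes only Zic1 (limma adjusted p = 0.00367) and Pi16 (0.0454) did. Aldh1a3 and C1qtnf7 (0.0563), Ddit4 (0.0602) and Tnnt2 and Cadm1 (0.075) missed there. Cxcl6 and Eln each missed in 4 of the fits that left out a 2W library (adjusted p up to 0.0813 without GelMA 2W replicate 2 and 0.0857 without MFN+GelMA 2W replicate 3). Meox1 missed in 1 (0.0537 without MFN+GelMA 2W replicate 1). Of all 12 fits that left out 1 library, Adamts4 missed in 7 and Timp1 in 9 (up to 0.135 and 0.153, both without GelMA 2W replicate 2).

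**Figure D2:**
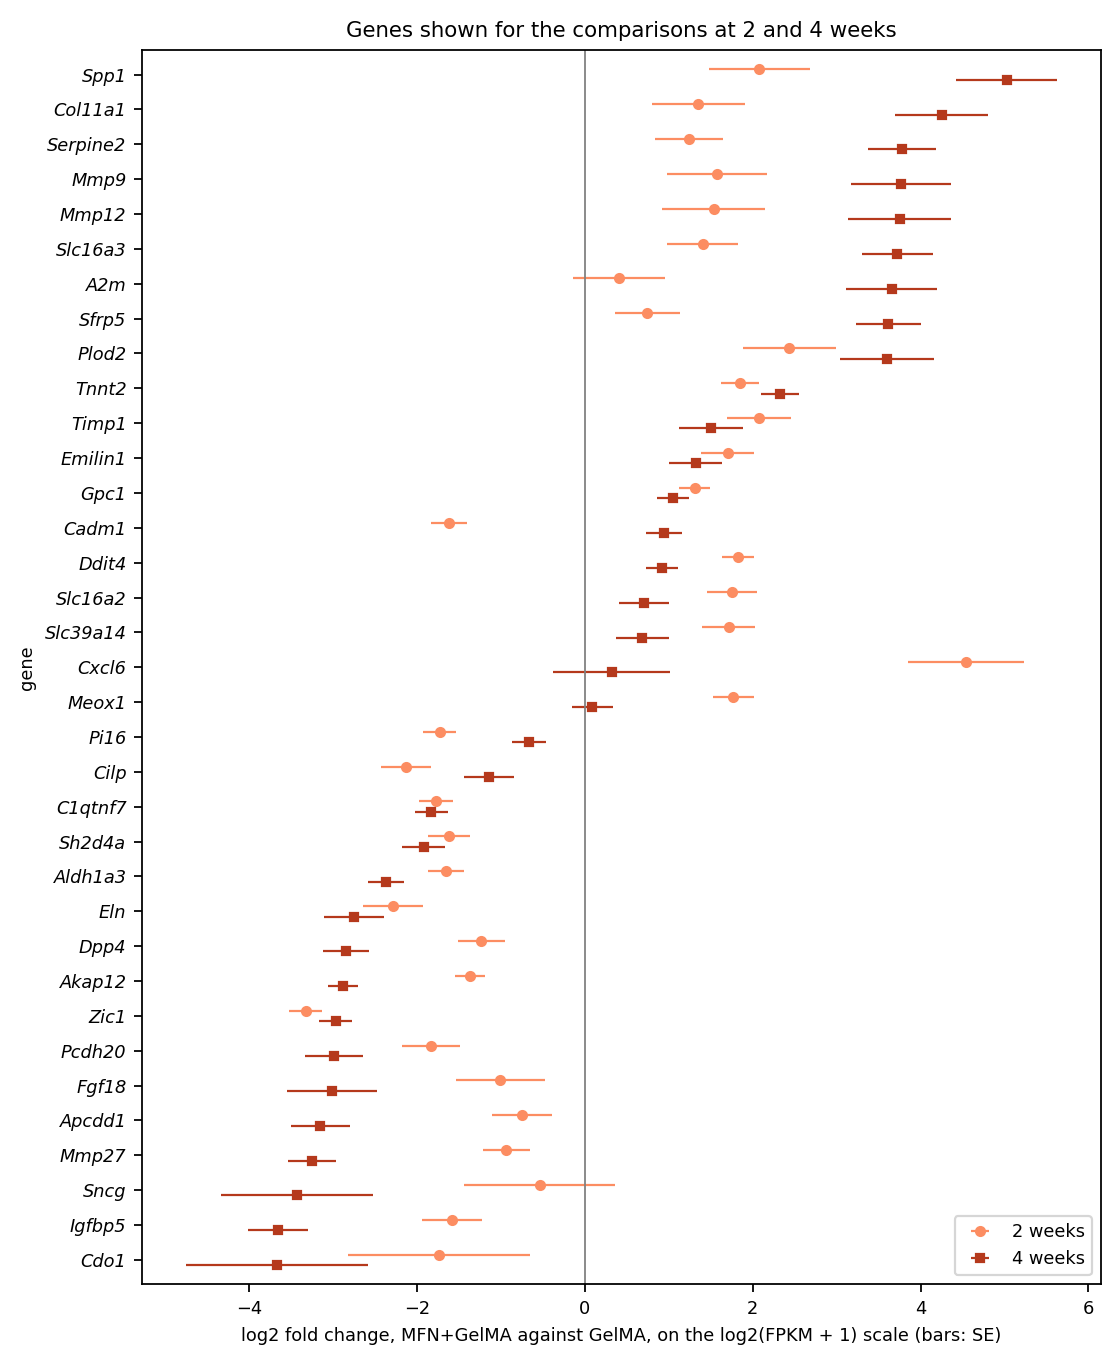
Log2 fold change of MFN+GelMA against GelMA (horizontal axis, log2(FPKM + 1) scale) for genes selected at 2 or 4 weeks, with values at 2 weeks (circles) and 4 weeks (squares), 1 gene per line; bars are SE from limma over 12 libraries. Spp1 lay at 5.03 at 4 weeks, Zic1 below -2.9 at both weeks, and Cadm1 on opposite sides of 0.

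At 4 weeks the same question had a larger answer. Genes of osteoclasts and of the multinucleated giant cells that form around implants rose in MFN+GelMA. Spp1, which encodes the matrix protein osteopontin, rose from 94.96 ± 72.6 FPKM (SD, n = 3) in GelMA 4W to 2614 ± 504.1 FPKM (SD, n = 3), and the gelatinase gene Mmp9 from 54.3 ± 58.4 to 517.3 ± 144.7 FPKM (SD, n = 3). The cell fusion gene Ocstamp rose from 0.456 ± 0.507 to 15.2 ± 4.56 FPKM (SD, n = 3), and Acp5, tartrate-resistant acid phosphatase, from 59.7 ± 20 to 204.2 ± 54.5 FPKM (SD, n = 3). Of the 12 tested genes of this list 11 rose, also when adjusted over the list alone, and 1, the integrin gene Itgb3 (6.81 ± 1.33 and 6.39 ± 1.8 FPKM, SD, n = 3), did not pass. The list's median log2 fold change was 1.74, with a camera adjusted p of 2.29e-06, and an adjusted p of 0.56 with an estimated correlation.

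By limma, Spp1 (ENSRNOG00000043451; rn6 chromosome 14, 6673685 to 6679901) changed by 5.03 on the log2 scale (SE 0.60, adjusted p = 0.00021) and Mmp9 (ENSRNOG00000017539; chromosome 3, 161413297 to 161421520) by 3.77 (SE 0.60, adjusted p = 0.00102). The limma values for Ocstamp and Acp5 were 3.48 (SE 0.32, adjusted p = 5.7e-05) and 1.78 (SE 0.24, adjusted p = 0.000413). The macrophage elastase gene Mmp12 rose from 218.4 ± 154.4 to 2481 ± 552.9 FPKM (SD, n = 3), Serpine2, an inhibitor of serine proteases, from 58.6 ± 41 to 697.6 ± 59.5 FPKM (SD, n = 3), and Sfrp5, a secreted Wnt antagonist gene, from 4.19 ± 1.99 to 59.7 ± 6.22 FPKM (SD, n = 3). Slc16a3, a lactate exporter gene, rose by 3.73, the collagen gene Col11a1 by 4.25, the collagen lysyl hydroxylase gene Plod2 by 3.60 and the protease inhibitor gene A2m by 3.65 on the log2 scale. The lower genes included Igfbp5, a binding protein of insulin-like growth factors, which fell from 1599 ± 352.7 to 131.8 ± 56.2 FPKM (SD, n = 3), and Dpp4, a peptidase of fibroblasts, which fell from 57.3 ± 19.6 to 7.05 ± 2.33 FPKM (SD, n = 3). Mmp27 fell by 3.25, the Wnt inhibitor gene Apcdd1 by 3.15, Fgf18 by 3.01, Pcdh20 by 2.98, Zic1 by 2.97 and the scaffold gene Akap12 by 2.88 on the log2 scale. Cdo1 (-3.67, SE 1.09, limma adjusted p = 0.0292) and Sncg (-3.43, SE 0.90, limma adjusted p = 0.0168) had GelMA 4W levels of 279.9 ± 437 and 471 ± 686.4 FPKM (SD, n = 3), in the group that held the library with high Adipoq.

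Macrophage, MHC class II and cell cycle genes were also higher in MFN+GelMA 4W than in GelMA 4W. Of 19 macrophage genes 12 rose (13 when adjusted over the list alone), led by Ptprc, the pan-leukocyte antigen CD45 (1.51 on the log2 scale), and the lysosomal membrane gene Laptm5 (1.27), with a camera adjusted p of 4.19e-05. Of 15 MHC class II genes 9 rose, over all genes and when adjusted over the list alone, among them Cd74, the invariant chain (1.10), and RT1-Da (1.32), with a camera adjusted p of 0.00482. Of 29 cell cycle genes 16 rose (18 when adjusted over the list alone), such as the spindle genes Nusap1 (1.08) and Kif20a, which shares its locus with Cdc23 (0.86), with a camera adjusted p of 4.19e-05. For these 3 lists the adjusted p was 0.56 with an estimated correlation. The alternative macrophage activation list moved the other way. Of its 18 genes 4 fell, among them Klf4, a transcription factor of that state (-1.65), and the haemoglobin scavenger receptor gene Cd163 (-1.57), and when adjusted over the list alone 6 fell and 1 rose, with a camera adjusted p of 0.0105 (adjusted p = 0.56 with an estimated correlation).

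Vessel genes fell. Of 18 endothelial genes 5 fell (12 when adjusted over the list alone), such as Nos3, endothelial nitric oxide synthase, whose locus overlaps Atg9b (-1.17 on the log2 scale), and Kdr (-1.30), with a camera adjusted p of 7.37e-05. Of 16 smooth muscle and pericyte genes 7 fell (9 when adjusted over the list alone), led by Abcc9 (-1.83) and Kcnj8 (-1.61), which encode a potassium channel complex of pericytes, with a camera adjusted p of 8.8e-05. Of 5 red blood cell genes 3 fell (5 when adjusted over the list alone), among them the globin gene Hba-a2 (-2.06) and Alas2, the first enzyme of haem synthesis in red cells (-1.03), with a camera adjusted p of 0.00589. For these 3 lists the adjusted p was 0.56 with an estimated correlation. With fry the endothelial and the smooth muscle and pericyte lists did not pass (adjusted p = 0.115 and 0.0603), and the red blood cell list did (0.0418). The mast cell list was lower (9 genes, median -1.03, none past the test, camera adjusted p = 0.0264; adjusted p = 0.66 with an estimated correlation and 0.194 with fry).

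A few further calls at 4 weeks rested on 1 library. The white adipocyte list was lower (19 genes, 1 rose and 2 fell, and 1 and 1 when adjusted over the list alone, median -2.18, camera adjusted p = 0.00911), with the complement gene Cfd, whose locus is shared with 16 other genes, at -2.49 and the lipase gene Lpl at 1.82 on the log2 scale. Without GelMA 4W replicate 2, the library with high Adipoq, its adjusted p was 0.132. The interferon-stimulated list was lower (24 genes, 2 fell, none when adjusted over the list alone, median -0.50, camera adjusted p = 0.0058), with Oas1a at -1.19 and Ifi27 at -0.87. Its adjusted p was 0.135 without the same library. Mitochondrial oxidative phosphorylation was higher (34 genes, 8 rose, also when adjusted over the list alone, median 0.22, camera adjusted p = 0.006), with the succinate dehydrogenase gene Sdhb at 0.64 and the complex I gene Ndufs1 at 0.64. Its adjusted p was 0.0783 without GelMA 4W replicate 3. For these 3 lists the adjusted p was 0.72 with an estimated correlation.

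In several other lists single genes changed in both directions while the list as a whole was not called by camera. The collagen and extracellular matrix list held 6 genes that rose and 6 that fell (7 and 6 when adjusted over the list alone), with Eln at -2.75 and the proteoglycan gene Dcn at -1.41. Its median (0.16) and mean (0.493) were raised by the listed zeros of Col1a1 and Col3a1. With these zeros as missing the median was -0.124 and the mean 0.0254. Camera ranked the list lower both with these 2 genes (adjusted p = 0.67) and without them (adjusted p = 0.487). In the matrix degradation list 9 rose and 7 fell (9 and 8 when adjusted over the list alone), including Ctss, a lysosomal protease gene of antigen-presenting cells, at 1.02 and Mmp19 at 1.05. Its mean (0.27) was positive while its median (-0.0531) and the camera direction were negative (adjusted p = 0.75). In the myofibroblast and TGF-beta list 8 rose and 6 fell (11 and 6 when adjusted over the list alone), with Tgfb1 at 0.78 and the latent TGF-beta binding gene Ltbp1 at -2.33 (camera adjusted p = 0.762). Of 21 pro-inflammatory genes 7 rose, also when adjusted over the list alone, among them the costimulatory gene Cd86 (1.54) and the chemokine gene Ccl3 (1.47), with a camera adjusted p of 0.0833. The Schwann cell and nerve list (10 genes, 4 rose, 1 fell; 6 and 2 when adjusted over the list alone) had Egr2 at 2.02, Cadm4 at 3.45 and S100b at -2.37 (camera adjusted p = 0.0916). Egr2, a myelination factor, is also a gene of activated immune cells. The cartilage and bone list (6 genes, 4 rose, 1 fell, also when adjusted over the list alone) had the osteoblast factor Runx2 at 1.65, Alpl at 1.51, Acan at 1.46 and Sost at -2.07 (camera adjusted p = 0.154). With fry the Schwann cell and nerve list and the cartilage and bone list did pass (adjusted p = 0.00794 and 0.00272). Camera with an estimated correlation gave an adjusted p of 0.56 for both. In the immediate early and heat shock list 2 rose and 4 fell, also when adjusted over the list alone, with Atf3 among the former and Hspa1b, whose locus is shared with 17 other genes, at -2.25 (camera adjusted p = 0.244). The neutrophil list had 1 gene higher and 1 lower, Il1r2 at -2.54 (camera adjusted p = 0.395), and the T cell list 1 higher of 17 (camera adjusted p = 0.75), with a positive mean (0.0118) beside a negative median (-0.0891) and camera direction. Both lists gave the same counts when adjusted over the list alone. The skeletal muscle fibre list had 1 lower of 11, and none when adjusted over the list alone (camera adjusted p = 0.472). The lists of keratinocytes, of B and plasma cells and of muscle regeneration had 4, 3 and 4 tested genes and were not tested as lists. Of these genes, Cdh3 in the first (1.30) and 3 in the last, led by Tnnt2 (2.33), rose, and when adjusted over the list alone 1 keratinocyte gene also fell.

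**Figure D3:**
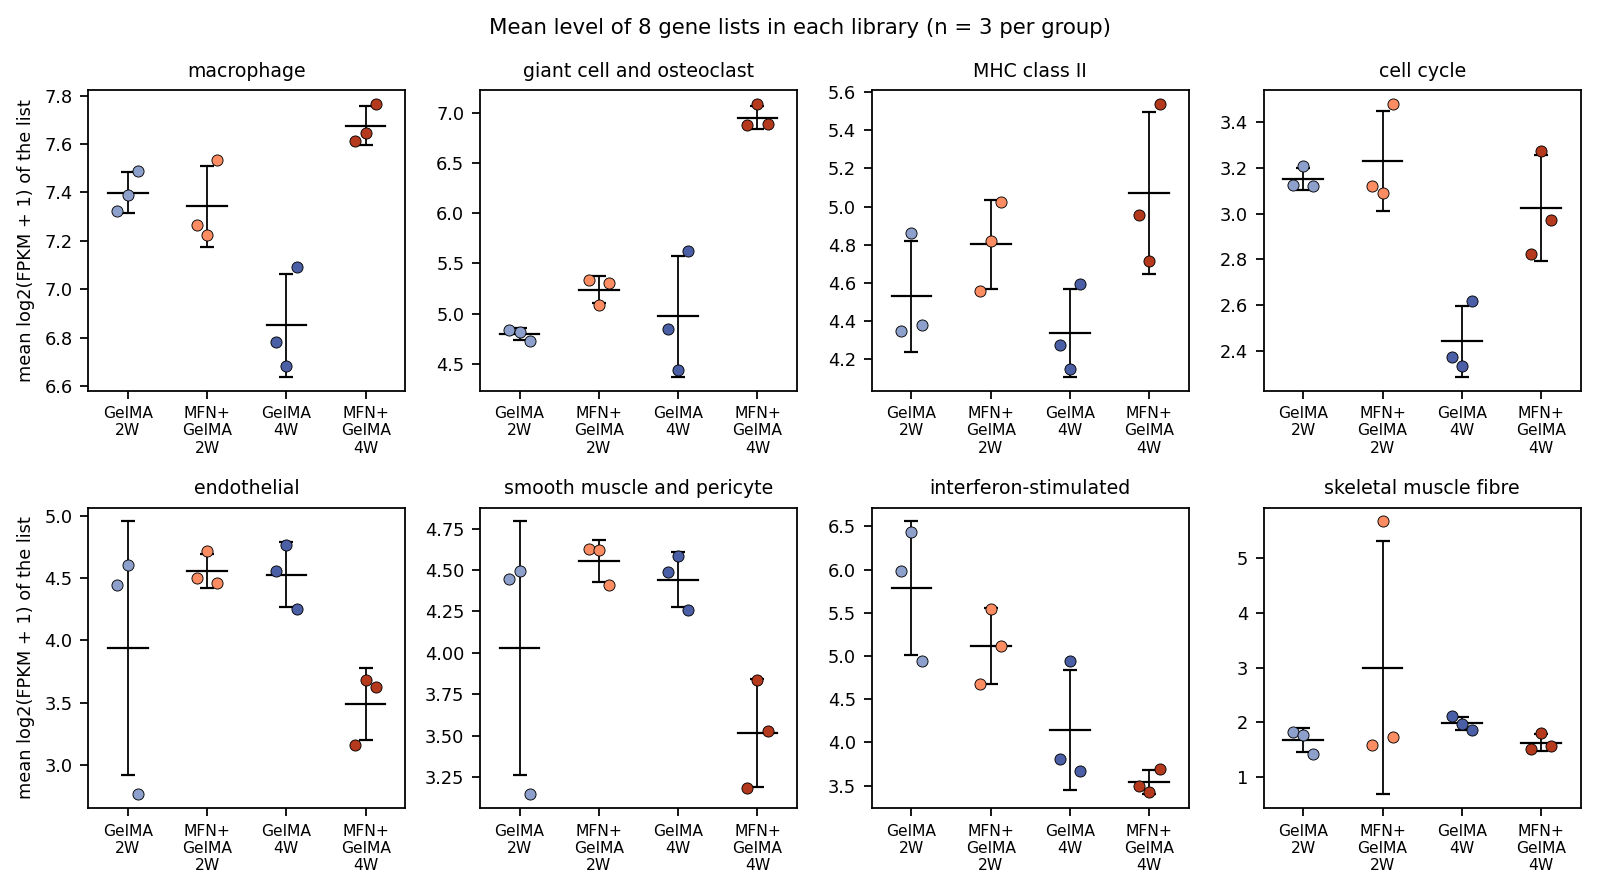
Mean log2(FPKM + 1) of the tested genes of 8 lists (vertical axes, each on its own range) in each library of the 4 groups (horizontal axes); points are libraries, lines are group means and bars are SD (n = 3). In MFN+GelMA 4W the giant cell and osteoclast list lay at 6.88 to 7.09 against 4.44 to 5.63 in GelMA 4W, and the skeletal muscle fibre list was high in 1 MFN+GelMA 2W library.

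At 4 weeks 3013 genes (24.6% of those tested) changed by limma, 1876 higher and 1137 lower, and 1173 of them by at least 2-fold. Of all tested genes 45.6% had groups that did not overlap, where chance would give 10%. Scaling each library's FPKM to the same total moved the split to 1294 higher and 1342 lower, so the balance of directions depended on the scaling. No single library moved the count by more than 1.5 times, but the calls of Kdr, Hba-a2, Alas2, Oas1a, Ifi27, Lpl, S100b, Cdo1 and Sncg were each lost without at least 1 of the libraries GelMA 4W replicate 1 or 2 and MFN+GelMA 4W replicate 1, 2 or 3, with adjusted p-values up to 0.101 (Ifi27 without MFN+GelMA 4W replicate 1). The smallest two-sided p that an exact test of 3 against 3 libraries can give is 0.1, so list levels per library were described and not tested.

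Genes changed at 2 weeks tended to change again at 4 weeks. The 2 comparisons shared no libraries in their group means, but both used 1 spread per gene estimated over all 12 libraries. Of the 21 genes higher at 2 weeks 10 were higher at 4 weeks, where independent lists would share 3.21 (Fisher's exact test, one-sided, p = 0.000474), and of the 40 lower genes 32 were lower again, against 3.71 (p = 2.16e-26). A shared spread can raise the overlap of calls but does not set their direction. Genes are also not independent, so these expected counts and p-values are only a rough guide. Zic1, Aldh1a3 and C1qtnf7 fell at both weeks, and Tnnt2 and Ddit4 rose at both. Zic1 stood at 11.8 ± 1.81 FPKM in GelMA 4W and 0.657 ± 0.402 FPKM in MFN+GelMA 4W (SD, n = 3). Cadm1 fell by 1.62 at 2 weeks and rose by 0.94 at 4 weeks on the log2 scale. The other genes called in opposite directions, named after their values were seen, were Aard (-2.02 and 0.90) and Glt8d2 (0.75 and -0.49). Without MFN+GelMA 2W replicate 1 Glt8d2 missed at 2 weeks (0.101), and without GelMA 4W replicate 1 Aard and Glt8d2 missed at 4 weeks (0.102 and 0.0782). Across all tested genes the fold changes of the 2 weeks had a Pearson's r of 0.22 and a Spearman's rho of 0.047.

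The interaction asked which effects of MFN differed between the weeks. Macrophage, giant cell and cell cycle genes gained relative to GelMA between 2 and 4 weeks, and vessel genes lost. The cell cycle list did not rise within MFN+GelMA. Its mean log2 level went from 3.23 to 3.02 there and from 3.15 to 2.44 in GelMA. The macrophage list went from 7.34 to 7.67 in MFN+GelMA and from 7.4 to 6.85 in GelMA. The macrophage list had 9 of 19 genes with a higher effect at 4 weeks (13 when adjusted over the list alone), such as Ptprc (1.76 on the log2 scale) and the Fc receptor subunit gene Fcer1g (1.18), with a camera adjusted p of 1.39e-05. The giant cell and osteoclast list had 7 of 12 (10 when adjusted over the list alone), including Ocstamp (2.55) and Gpnmb (1.70), with a camera adjusted p of 1.09e-05, and the cell cycle list 6 of 29 (10 when adjusted over the list alone), led by Kif20a (1.11), with a camera adjusted p of 0.00104. The endothelial list had 3 of 18 genes with a lower effect (14 when adjusted over the list alone), such as Nos3 (-2.33), and the smooth muscle and pericyte list 6 of 16 (13 when adjusted over the list alone), such as Kcnj8 (-1.84) and Abcc9 (-1.50), both lists at a camera adjusted p of 5.14e-07. These vessel lists were also low in GelMA 2W replicate 3, and both kept their calls without it. With an estimated correlation the adjusted p of these 5 lists was at least 0.53. With fry the macrophage and giant cell lists passed (adjusted p = 0.0181 each). The cell cycle, endothelial and smooth muscle lists did not pass with fry (adjusted p = 0.0909, 0.0808 and 0.0723).

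Cxcl6 and Lcn2, genes of neutrophil recruitment and defence, had lower effects at 4 weeks, with differences of -4.22 (SE 0.98, limma adjusted p = 0.0178) and -4.87 (SE 0.96, limma adjusted p = 0.00938) on the log2 scale. Lcn2 stood at 14.5 ± 9.15 and 188.9 ± 193.2 FPKM (SD, n = 3) in GelMA and MFN+GelMA at 2 weeks and at 15.1 ± 3.37 and 5.01 ± 2.22 FPKM (SD, n = 3) at 4 weeks. Cst6, a cysteine protease inhibitor gene, had an effect higher by 3.45 (SE 0.61, limma adjusted p = 0.00675), with 8.28 ± 1.94 and 56.0 ± 23.2 FPKM (SD, n = 3) at 4 weeks, and the tight junction gene Cldn4 by 3.29 (SE 0.43, limma adjusted p = 0.00291). Ret, a receptor tyrosine kinase gene, had an effect lower by 2.67 (SE 0.41, limma adjusted p = 0.0044). Parvalbumin, encoded by the muscle list member Pvalb, had the most negative interaction among the genes selected for naming (-4.96). It stood at 0.931 ± 1.03 and 17.6 ± 25.2 FPKM (SD, n = 3) in GelMA and MFN+GelMA at 2 weeks and at 9.35 ± 3.72 and 0.751 ± 0.964 FPKM (SD, n = 3) at 4 weeks. Without MFN+GelMA 2W replicate 2, the library with muscle, the interaction of Pvalb was still called (limma adjusted p = 0.0148). The neutrophil list (2 of 7 lower, 3 when adjusted over the list alone), the alternative macrophage list (2 of 18 lower, also when adjusted over the list alone, among them Cd163 at -2.10), the skeletal muscle list (1 of 11 lower, also when adjusted over the list alone) and the red blood cell list (none of 5 past the test) each had a camera adjusted p of 0.0178 with lower effects at 4 weeks. Their adjusted p-values with an estimated correlation were 0.53 to 0.66. Calls were lost without MFN+GelMA 2W replicate 2 for muscle (0.433), GelMA 2W replicate 2 for neutrophils (0.0501) and MFN+GelMA 2W replicate 3 for alternative activation (0.059).

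In all, the effect differed between the weeks for 1727 genes by limma, higher at 4 weeks for 1116 and lower for 611, and scaling to the same total made this 703 and 601. The count was 925 without GelMA 4W replicate 1, 1096 without MFN+GelMA 4W replicate 1 and 1126 without MFN+GelMA 4W replicate 3. Of the 20 genes selected for naming 11 passed in every fit that left out 1 library, and Pvalb missed without GelMA 2W replicate 1, GelMA 4W replicate 1 (0.0571) or MFN+GelMA 4W replicate 1. Abcc9 missed without either of the last 2 (up to 0.0565, without GelMA 4W replicate 1).

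Averaged over both weeks, the giant cell and osteoclast, macrophage, MHC class II and cell cycle lists were higher in MFN+GelMA. Of their 12, 19, 15 and 29 genes 9, 7, 7 and 9 rose. When adjusted over the list alone 10, 9, 8 and 14 rose and 1 giant cell gene fell. Examples were Ocstamp at 2.21, the lysozyme gene Lyz2 at 0.97, Cd74 at 0.97 and Cdk1 at 0.68 on the log2 scale. Of these 4 lists only MHC class II was called at 2 weeks as well. There the macrophage list had a median log2 fold change of -0.162 with 14 of 19 genes at negative values (camera adjusted p = 0.188). The giant cell and cell cycle lists had medians of 0.421 and 0.0643 (camera adjusted p = 0.187 and 0.397), with none of the genes of these 3 lists past the test over all genes (4 giant cell genes rose and 2 fell when adjusted over the list alone). The interferon-stimulated list was lower (2 of 24 fell, 1 when adjusted over the list alone), with Oas1a at -1.11. Tnn, which encodes the matrix protein tenascin-N, rose by 3.01, and Pcsk6, a proprotein convertase gene, fell by 2.11 on the log2 scale. The camera adjusted p was 5.63e-06 for the giant cell and the interferon-stimulated lists, 6.63e-05 for the cell cycle, 0.0015 for MHC class II and 0.00229 for macrophages. Oxidative phosphorylation (8 of 34 rose, 9 when adjusted over the list alone, adjusted p = 0.000554) was also higher, and white adipocyte (3 of 19 fell, 7 when adjusted over the list alone, adjusted p = 0.00229) and red blood cell genes (none of 5 past the test, adjusted p = 0.0175) were lower. The pro-inflammatory list was higher (2 of 21 rose, 8 when adjusted over the list alone, adjusted p = 0.0356) and the alternative macrophage list lower (2 rose and 3 fell, 4 and 3 when adjusted over the list alone, adjusted p = 0.0465). Both were lost in 6 of the 12 fits that left out 1 library, up to 0.111 without MFN+GelMA 2W replicate 3 and 0.157 without MFN+GelMA 2W replicate 2. With an estimated correlation no list had an adjusted p under 0.63. By limma 1855 genes changed, 1185 higher and 670 lower, or 740 and 730 after scaling to the same total. The fat hormone genes Adipoq (-3.93, SE 1.12, limma adjusted p = 0.0366) and Retn (-3.10, SE 0.81, limma adjusted p = 0.0242) were among the lower genes and missed in 7 and 5 of the 12 fits that left out 1 library (up to 0.0897 and 0.0597, both without GelMA 2W replicate 2).

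The time comparisons asked what changed from 2 to 4 weeks within each material. In GelMA, interferon-stimulated and dividing-cell genes fell. Of 24 interferon-stimulated genes 10 fell (20 when adjusted over the list alone), such as the antiviral genes Oasl (-2.02 on the log2 scale), Usp18 (-1.52) and Oas1a (-1.86), and the transcription factor gene Irf7, which shares its locus with Phrf1, went from 280.8 ± 93.7 to 51 ± 49.1 FPKM (SD, n = 3). Mx1 went from 183.9 ± 113.4 to 23.5 ± 27 FPKM (SD, n = 3), and Siglec1, an interferon-induced receptor gene of macrophages, from 86.98 ± 16.3 to 18.6 ± 10.7 FPKM (SD, n = 3). Of 29 cell cycle genes 9 fell (22 when adjusted over the list alone), including Nusap1 (-1.10) and Tpx2 (-0.99). Of 19 macrophage genes 4 fell (11 when adjusted over the list alone), such as Adgre1 (-1.11), and of 21 pro-inflammatory genes 3 fell (6 when adjusted over the list alone), such as the inflammasome gene Nlrp3 (-1.07) and Tlr2 (-1.01). Camera gave adjusted p-values of 4.98e-16, 7.08e-17, 8.15e-08 and 2.25e-06 for these 4 lists, which with an estimated correlation were adjusted p = 0.49, 0.36, 0.36 and 0.57.

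Higher in GelMA at 4 weeks were the oxidative phosphorylation list (34 genes, median 0.25, 1 rose, also when adjusted over the list alone, Ndufb5 at 0.48, camera adjusted p = 4.13e-07) and 4 lists that moved with the libraries standing apart. These were white adipocyte (19 genes, median 1.24, 1 rose, camera adjusted p = 0.000149), whose adjusted p without GelMA 4W replicate 2 was 0.961 in the opposite direction, and endothelial (median 0.58, adjusted p = 0.000817), smooth muscle and pericyte (median 0.46, adjusted p = 0.00701) and mast cell genes (median 0.70, adjusted p = 0.0352), whose adjusted p-values without GelMA 2W replicate 3 were 0.543, 0.783 and 0.783. The mast cell list also lost its call without GelMA 4W replicate 2 (0.0945). The mean of the oxidative phosphorylation list was also highest in GelMA 4W replicate 2, at 6.367 on the log2 scale. It was 5.922 and 5.846 in GelMA 4W replicates 1 and 3 and 5.699 to 5.842 in GelMA 2W, so much of its rise lay in that library. With an estimated correlation the adjusted p of these 5 lists was at least 0.69. The angiopoietin gene Angpt4 (1.66 on the log2 scale), Apcdd1 (1.70) and Ccl24 (1.46) were among the genes that rose. Mzt1 was listed at 0 in all 6 libraries of 2 weeks and at 7.14 ± 5 FPKM (SD, n = 3) in GelMA 4W.

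In GelMA 274 genes changed with time by limma, 61 higher and 213 lower (37 and 292 after scaling to the same total), and 2233 had an unadjusted p under 0.05. The count was 12 without GelMA 4W replicate 1, 28 without GelMA 2W replicate 1, 85 without GelMA 2W replicate 2 and 173 without MFN+GelMA 4W replicate 3, so these gene calls rest on single libraries. Of the 20 genes selected for naming 0 passed in every fit that left out 1 library, with adjusted p-values without GelMA 4W replicate 1 of 0.0504 for Siglec1, 0.149 for Irf7, 0.177 for Mx1 and 0.204 for Ccl24. Oasl and the 4 lists that fell were called in all of these fits.

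In MFN+GelMA, interferon-stimulated genes fell too, and giant cell genes rose. Of 24 interferon-stimulated genes 14 fell (21 when adjusted over the list alone), including Oas1a (-2.01 on the log2 scale), Ifi27 (-1.49) and Cxcl10, which went from 51.2 ± 19.7 to 4.01 ± 2.4 FPKM (SD, n = 3) and shares its locus with Art3 and Cxcl11. Of 12 giant cell and osteoclast genes 10 rose, also when adjusted over the list alone, among them Acp5 (2.32) and the lipid-sensing receptor gene Trem2 (2.20). Of 34 oxidative phosphorylation genes 13 rose, also when adjusted over the list alone, such as Sdhd (0.54) and Sdhb (0.60). Smooth muscle and pericyte genes fell in 7 of 16 cases (14 when adjusted over the list alone), with Kcnj8 at -1.68, and endothelial genes in 6 of 18 (9 when adjusted over the list alone), with Sox18 at -2.02 and Nos3 at -1.39. Camera gave adjusted p-values of 9.6e-10, 4.06e-07, 2.99e-06, 5.15e-06 and 2.52e-05 for these 5 lists, and with an estimated correlation adjusted p was 0.42 or 0.43. With fry the adjusted p was 0.0686 for the endothelial list and at most 0.0323 for the others.

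Cd163 fell from 98.1 ± 49 to 10.2 ± 2.04 FPKM (SD, n = 3) and led the alternative macrophage list, in which 7 of 18 genes fell (8 when adjusted over the list alone), among them the mannose receptor gene Mrc1 (-0.84; camera adjusted p = 0.000109, and adjusted p = 0.42 with an estimated correlation). Of 28 collagen and matrix genes 9 fell and 1 rose (11 and 1 when adjusted over the list alone), with Dcn at -1.18 and Fbn1 at -1.28 (camera adjusted p = 0.000843, and adjusted p = 0.43 with an estimated correlation). The T cell genes Cd8a (-2.84) and Cd8b (-1.16) fell with 2 others of 17 (camera adjusted p = 0.0138), and the neutrophil genes Lcn2 (-4.58) and Csf3r (-1.60) with 1 other of 7 (camera adjusted p = 0.00437). Adjusted over the list alone these counts were the same. Of 10 Schwann cell and nerve genes 4 rose (6 rose and 1 fell when adjusted over the list alone), led by Egr2 (1.87) and Pmp22 (0.97; camera adjusted p = 0.00604). Pro-inflammatory genes went both ways, 3 higher and 5 lower of 21 (4 and 12 when adjusted over the list alone), with Il1b at -2.59 and Cd86 at 1.76 (camera adjusted p = 0.0256). Of 29 cell cycle genes 2 fell, and none when adjusted over the list alone, among them Birc5 (-0.73; camera adjusted p = 0.0235). The red blood cell list (1 of 5 lower, 3 when adjusted over the list alone, Hba-a3 at -1.43, camera adjusted p = 0.0161) and the skeletal muscle list (none of 11 past the test, median -1.23, camera adjusted p = 0.0192) were also lower. No list of the time comparison in MFN+GelMA had an adjusted p under 0.42 with an estimated correlation. Calls were lost without MFN+GelMA 2W replicate 2 for muscle (0.848), without MFN+GelMA 2W replicate 3 or 4W replicate 2 for pro-inflammatory genes (0.132 and 0.0521), and without MFN+GelMA 2W replicate 3 or 4W replicate 1 or 3 for the cell cycle (0.306, 0.123 and 0.0815).

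In MFN+GelMA 2367 genes changed with time by limma, 1372 higher and 995 lower, and scaling to the same total, which shifted the median of all genes to -0.122 on the log2 scale, made this 825 and 1402. Cst6 rose by 4.55 (SE 0.43, limma adjusted p = 0.000165), the metallothionein gene Mt3 by 4.38 (SE 0.72, limma adjusted p = 0.00183) and Hspb7, a small heat shock protein gene of muscle, by 3.47 (SE 0.35, limma adjusted p = 0.000196), while the complement gene Cfb, whose locus is shared with Nelfe and C2, fell by 4.23 on the log2 scale (SE 0.63, limma adjusted p = 0.00113). Of the 20 genes selected for naming 19 passed in every fit that left out 1 library. The count was 1506 without MFN+GelMA 4W replicate 1 and 1540 without MFN+GelMA 4W replicate 3, and the calls of Birc5 and Hba-a3 were each lost without either of them (up to 0.12 and 0.143, both without MFN+GelMA 4W replicate 1). The same libraries of a group served in more than 1 comparison, so calls of the time comparisons and of the comparisons between materials are not independent.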

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

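The tests of fat, of macrophage share, of listed zeros, of body site and of muscle tissue below were chosen only after the results were seen, and of these only the body site test on the average over both weeks was written before its own value was known.

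A test of the interaction found effects of MFN+GelMA that differed between 2 and 4 weeks, for 1727 genes by limma and for 9 gene lists by camera. The adjusted p-values of the lists were 1.39e-05 for macrophage, 1.09e-05 for giant cell and osteoclast, 0.00104 for cell cycle, 5.14e-07 for endothelial and also for smooth muscle and pericyte, and 0.0178 each for skeletal muscle fibre, neutrophil, alternative macrophage activation and red blood cell genes. None of the 9 was called with an estimated correlation, where the lowest adjusted p was 0.53. Fry called 2 of them, macrophage and giant cell and osteoclast. Among the named genes, the difference of log2 fold changes was 4.45 for Stra13, 3.45 for Cst6, 3.3 for Fcgr3a, 3.29 for Cldn4, 3.28 for Faim, 3.27 for Pxt1, 3.24 for A2m, 2.94 for Spp1, 2.9 for Col11a1 and 2.87 for Sfrp5. It was -4.96 for Pvalb, -4.87 for Lcn2, -4.22 for Cxcl6, -3.12 for Cfb, -2.87 for Mme, -2.77 for Prnd, -2.76 for Art3, -2.67 for Ret and Gpihbp1 and -2.57 for Adgrv1. Among the list genes it was 1.76 for Ptprc, 1.18 for Fcer1g, 2.55 for Ocstamp, 1.7 for Gpnmb and 1.11 for Kif20a. It was -2.33 for Nos3, -1.84 for Kcnj8, -1.5 for Abcc9, -1.95 for Il1r2, -2.1 for Cd163 and -1.03 for Klf4. Stra13 and Pxt1 were listed at 0 in all MFN+GelMA 2W libraries, and the loci of Fcgr3a, Cfb and Art3 are shared with 1, 2 and 2 other genes. Of the first 20 genes 9 missed the threshold without at least 1 library, up to an adjusted p of 0.115 for Fcgr3a without GelMA 4W replicate 1.

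For the interaction (1727 genes) 4 of 100 drawn splits of the libraries within each week gave as many genes, the real one included, and for the average over both weeks (1855 genes) 2 of 100 did, with 1929 as the highest count of another split in each case. Every other split that gave as many had kept the 4W groups, 3 of 9 such splits for the interaction and 1 of 9 for the average, while no split that broke them up called more than 1 gene. The counts thus followed the structure of the 4W libraries, and these splits do not exclude chance for the grouping of the 2W libraries. For the other 4 comparisons 10 splits are too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many genes, with 61 against at most 1 in the others at 2 weeks, 3013 against 1 at 4 weeks, 274 against 2 for time in GelMA and 2367 against 1 for time in MFN+GelMA.

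The rise of giant cell and osteoclast genes in MFN+GelMA at 4 weeks may reflect more such cells around the implant. Without GelMA 4W replicate 2, the library with the most Adipoq, the median log2 fold change of the list was 1.4, against 1.74 with it. Under 3 scalings of the FPKM it was 1.59 or more. These values argue against the fat of that library and against scaling as the whole source. Fat in the other GelMA 4W libraries was not removed. Adipoq stood there at 17.97 FPKM or more, against at most 10.35 FPKM in MFN+GelMA 4W. A larger share of macrophages alone would raise both lists alike, but the mean of the giant cell list minus that of the macrophage list was higher by 1.16 on the log2 scale in MFN+GelMA 4W (-0.881 to -0.557 per library) than in GelMA 4W (-2.24 to -1.46). This argues against such a share as the whole source, in a comparison set up when both lists' values were known and with too few libraries for a test. A changed state of the macrophages present stays open, and no count of cells was tested.

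The loss of Zic1 in MFN+GelMA at both weeks could come from tissue taken at another body site or layer, since this gene marks position. Of 26 other tested patterning genes 7 (26.9%) were called in the average over both weeks against 15.1% of all other genes (Fisher's exact test, one-sided, p = 0.086). By week, counted after the weeks had been seen, 15 of the 26 were called at 4 weeks, all lower (57.7% against 24.5% of all other genes, Fisher's exact test, one-sided, p = 0.00031), and 0 at 2 weeks, where 0.13 would be called at the share of other genes and the median log2 fold change was 0.0048, so a difference in site and an effect of the material cannot be told apart. Of the 26 genes 16 were Hox genes, and genes are not independent, so both Fisher p-values are only a rough guide. Failed estimates do not account for the loss of Zic1, as 5 of the 6 MFN+GelMA libraries listed the gene above 0, with values of 0 to 1.08 FPKM there and 9.86 to 13.8 FPKM in GelMA. The material itself, the difference the design names, stays open and untested apart from site.

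Skeletal muscle genes stood out in MFN+GelMA 2W replicate 2. All 11 tested fibre genes were highest in that library, 9 of them over 4-fold above each of the other 11 libraries, with Myl1 at 146 against at most 1.42 FPKM elsewhere, which is consistent with muscle tissue in that sample. No biological explanation was tested for it, as the labels name subcutaneous tissue or muscle for every sample.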

How the results depend on the processing

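The fits with 2 or 3 libraries left out, the Counts columns, the fat covariate and the collagen list without Col1a1 and Col3a1 were chosen after the data had been seen. The counts at 2 weeks and for time in GelMA were the least steady; where no construction is named, the cause was not tested. For the 61 genes at 2 weeks, fits with fewer libraries gave 9 (only the 6 compared), 244 (2 libraries with muscle or fat out, 60 genes shared) and 386 (3 out, 56 shared), array weights gave 95, a muscle covariate 152, a fat covariate 142, the Counts columns 104, a threshold of 0.1 gave 249, and unadjusted p with 2-fold 261. For time in GelMA (274), the counts were 4 (only the libraries compared), 837 (array weights), and 623 (threshold of 0.1). Unadjusted p with 2-fold gave 1342 against 3013 at 4 weeks, 464 against 1855 for the average and 926 against 2367 for time in MFN+GelMA, and a threshold of 0.1 gave 2605 against 1727 for the interaction. Of 65 list calls 0 held with an estimated correlation. Fry made 28 calls, not all of them among these 65. Cartilage and bone passed with fry alone at 4 weeks, in the average and for time in MFN+GelMA (fry adjusted p = 0.00272, 0.0112 and 0.00523). So did Schwann cell and nerve at 4 weeks (0.00794) and matrix degradation in the average (0.0451). Same-numbered deviations correlated at -0.04 to 0.081 between materials and -0.058 to 0.37 between weeks. Between weeks, GelMA replicates 2 and 3 had 0.31 and 0.37, while replicate 2 against 3 had -0.34 in either order. With 3 libraries per group, and labels that do not say what the numbers share, these values cannot exclude a pairing. With a replicate block the counts were 6 at 2 weeks (5 shared) and 2558, 1452, 1179, 271 and 2335 in the other contrasts, with 70 list calls. At 2 weeks Zic1 passed with that block (limma adjusted p = 0.00617), while Aldh1a3 and Pi16 (0.0588) and Ddit4, Tnnt2, C1qtnf7 and Cadm1 (0.0602) missed.

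Leaving out 1 library at a time gave 22 to 162 genes at 2 weeks, 2014 to 3315 at 4 weeks, 1269 to 1977 for the average, 925 to 1612 for the interaction, 12 to 290 for time in GelMA, 1506 to 2629 for time in MFN+GelMA and 62 to 70 list calls. Lists changed direction when the libraries that carried them were corrected for or removed. With its own level as a covariate, which removes that level by construction, the skeletal muscle list had a camera adjusted p of 0.693 at 2 weeks and 0.738 in the interaction. Those values are therefore no check of its call. At 2 weeks its adjusted p was 0.71 without MFN+GelMA 2W replicate 2 (as low as 1.6e-05 without replicate 1 of that group) and 0.717 with 3 libraries out. With those 3 out the endothelial list at 2 weeks had 0.992, and for time in GelMA the mast cell list had 0.756, the endothelial and smooth muscle lists 0.735 each and the white adipocyte list 0.00363, now lower, after 0.961 without GelMA 4W replicate 2 (as low as 4.45e-08 without GelMA 4W replicate 1). Of 7390 values of genes selected for naming over the alternatives 6769 kept direction and side of the threshold, 621 kept the direction only and 0 reversed. These genes were selected in the fit over all 12 libraries, and the alternatives reused those libraries. Some alternatives, such as the replicate block, left the log2 fold changes as they were. Few reversals could therefore arise, so these counts are not an independent check.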

Other observations

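The pathway and hypoxia tests and the set of patterning genes below were chosen only after the results were seen.

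The pathway names in the deposited table gave 275 sets of at least 10 tested genes, of which camera called 25 at 4 weeks, 21 higher and 4 lower. The set of collecting duct acid secretion, which holds proton pump subunits, had 11 of 17 genes higher and 0 lower in MFN+GelMA (adjusted p = 0.000112), the phagosome set 54 higher and 7 lower of 130 (0.000265), the lysosome set 40 and 4 of 110 (0.000291) and the osteoclast differentiation set 45 and 9 of 111 (0.000399). Cytochrome P450 drug metabolism had 13 of 30 genes lower and 2 higher (0.000412). With an estimated correlation the adjusted p of each of these sets was 0.92.

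From 2 to 4 weeks, antigen processing and presentation was lower in GelMA (10 of 64 genes fell and 1 rose, camera adjusted p = 4.59e-08), and oxidative phosphorylation (36 of 107 rose and 3 fell, 9.99e-08) and the citrate cycle (13 of 28 rose and 1 fell, 0.000505) were higher in MFN+GelMA. Oxidative phosphorylation and the citrate cycle were also called higher in GelMA by camera (adjusted p = 3.87e-07 and 0.000216), with 2 and 0 genes past the limma test. Among the GelMA libraries, the oxidative phosphorylation list fixed in advance stood highest in GelMA 4W replicate 2, the library with high Adipoq. No set was called with an estimated correlation. Of the patterning genes, Irx3 (-1.32), Prrx2 (-1.09), Hoxc4 (-1.03), Hoxc8 (-0.82), Meox2 (-0.77), Hoxc6 (-0.52) and Tbx15 (-0.48) were lower on the log2 scale in the average over both weeks, the 7 called of 26, while 15 of the 26 were lower at 4 weeks and 0 passed at 2 weeks. The call of Hoxc6 in the average was lost without GelMA 4W replicate 1 (limma adjusted p = 0.0534).

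A candidate explanation for the rise of Slc16a3 and Plod2 at 4 weeks is a hypoxia response in MFN+GelMA. In a list of 23 hypoxia-inducible genes, chosen after the results were seen, 15 rose at 4 weeks and 0 fell. Its median log2 fold change was 0.834, with an unadjusted camera p of 8.4e-07 (0.048 with an estimated correlation). This list was tested alone, so its p-values were not adjusted over lists. The giant cell list at 4 weeks had the same unadjusted camera p of 0.048 with an estimated correlation, which was 0.56 when adjusted over the lists. Eno1 (1.66), Pgk1 (1.35), Ldha (1.24) and the glucose transporter gene Slc2a1 (2.36) rose, while Vegfa, which hypoxia also induces, was at -0.56 (limma adjusted p = 0.131). At 2 weeks 0 of the 23 passed (median 0.212, camera p = 0.022, and 0.31 with an estimated correlation; 1 rose when adjusted over the list alone). At 4 weeks genes outside glycolysis rose too, such as Egln3 (1.24), Ndrg1 (1.23) and P4ha1 (1.02 on the log2 scale). Others, among them Adm, Bnip3, Ankrd37 and P4ha2, did not pass the limma test. Glycolysis genes also rise in activated macrophages, and the list was tested as a whole, so it does not separate hypoxia from a change of cell state.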
